A study of Mus musculus with 8 samples.

How the data were processed

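Nuclei were isolated from flash-frozen brain tissue, labelled as cortex, of C57BL/6 mice aged 2 years, and single-nucleus RNA libraries were sequenced. Per the labels' protocols, nuclei were spun through a sucrose cushion that separates them from myelin debris, so every share of nuclei given here is a share of the nuclei recovered. The 8 samples fall into 4 labelled WT and 4 labelled KΔ75, a loss-of-function mutant of DAP12. The labels number the samples of each genotype from 1 to 4 but do not say that each came from a separate animal, so p-values measure the spread between these samples, which may be partly technical.

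The authors deposited raw UMI counts per nucleus, whole numbers without normalization, together with a table that gives the sample, library name, cell class and cluster of each nucleus. Cell Ranger 3.1.0, Seurat and the genome build GRCm38 (mm10) are named per the submitters' processing notes, without the role of each. The deposited counts cover 60851 nuclei and 25167 rows. The total UMI counts and detected rows that the authors deposited for each nucleus were equal to those recomputed from the count table in all 60851 nuclei. Each nucleus had at least 1001 UMIs and 701 detected rows, and each row was detected in at least 3 nuclei, so the authors had filtered the table before they deposited it. The mitochondrial fraction of each nucleus is the authors' value, per the file headers, and reached at most 2.99% of the UMIs of a nucleus. The 10 cell classes and 35 clusters are the authors' annotation. Each of the 35 clusters holds nuclei of a single class.

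The count table carries no gene names, and the files do not pair its rows with genes. Rows are therefore identified by their number in the table, and at most 2 rows that rose and 2 that fell are named. The level of Tyrobp, the gene for DAP12, could not be used to check the genotype labels, and marker genes, gene lists and a sex covariate were not used here. The rows counted in the mitochondrial fraction could be found from the data. Among rows with at least 1000 UMIs, 13 never exceeded the mitochondrial UMIs of any nucleus, and their sum lay within 1 UMI of the deposited fraction times the total in 100% of nuclei.

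UMI counts were summed per sample and cell class, leaving out a sample with fewer than 10 nuclei of a class. Sums were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, robust fit), with TMM normalization and edgeR's filter on low counts, genotype as the only term, and Benjamini-Hochberg adjustment within each class at 0.05. Levels are given in CPM (UMIs of a row scaled to a fixed library total) of the class, and log2 fold changes are KΔ75 minus WT. Shares of nuclei and yields per sample were compared with two-sided exact permutation tests over all 70 arrangements of the 8 samples, which cannot give a p below 0.0286, and adjusted over the classes or measures. Where a row had no UMI in a group, the fold is a lower bound against 3 counts over the whole group. Ratios of small counts carry an exact Poisson interval at 95% confidence, which covers counting error only.

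In place of gene lists, sets of class-enriched rows were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and with fry as alternatives. A row entered the set of a class at a mean of 10 CPM or more over the 8 samples and at least 4 times its level in the other classes. Neuron-enriched rows (220 rows) met this in both neuron classes against the 4 glial classes. A first definition against all other classes had left 1 row, so the comparison classes were changed after the data were seen. A further set of 4470 rows varied less than 4-fold between all classes. These sets were chosen from the same libraries, after seeing the data, and are not independent of them. Over all classes 122 set tests were run, of which 45 passed with the preset and 8 of these also with an estimated correlation.

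The design, the alternatives and the rule for the rows that are named were fixed before the data were examined. That rule takes, among rows that pass the test with at least 20 CPM in a genotype, those of smallest p in each direction. It was written for more genes per class, plus named genes of microglia, oligodendrocytes and astrocytes, and is applied here to 2 rows per direction over all classes because the rows have no names. Alternatives fixed then were DESeq2's size factors, no filter on low counts, each sample left out in turn, the replicate number as a block, counts thinned to the shallowest sample, DESeq2 1.42.0 (Wald test), rows at 0.1 or more of their highest class, and 1 adjustment over all classes.

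Further alternatives were chosen after seeing the data. The library names begin with M_JE in all 4 WT and in KΔ75 samples 1 and 2, and with BCAE in KΔ75 samples 3 and 4. The library name was therefore used as a term, and the M_JE and the BCAE libraries were also compared separately with WT. Fits with 2 surrogate variables (sva 3.50.0) and fits restricted to the 60632 nuclei on which a second clustering of the authors gave the same class were added. Suspected doublets were marked without marker genes, as the top 2% of UMIs of a class or as nuclei holding at least 5 UMIs of another glial or vascular class's rows at 25% or more of that class's median share. This left out 2313 nuclei.

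Summed counts per sample ran from 74925912 UMIs in KΔ75 4 to 121210544 in WT 1. Per class, power was tested on simulated data drawn from the real means, library sizes and spread with 200 changed rows. In excitatory neurons (18391 rows) edgeR recovered 46.3% of 2-fold and 95.5% of 4-fold changes with 7 false calls, against 55 false calls with DESeq2. In microglia (9524 rows) it recovered 50.8% of 2-fold and 84.9% of 4-fold changes with 4 false calls, and in the class Endo (3421 rows) 20.9% and 75.8% with 1 false call. At 1.5-fold, recovery was 8.96% in excitatory neurons and 4.48% in microglia, so changes of that size were mostly not detectable. Rows were simulated independently, without differences that groups of samples share. The real libraries hold such differences, so the simulated false calls do not give the error rate of the real fits. Within each genotype, the summed counts of excitatory neurons were compared between samples over rows with at least 20 UMIs. Every pair differed by far more than sampling noise, so no library was counted as a repeat of another.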

Results

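Single-nucleus RNA profiles of the cortex of 2-year-old mice were compared between WT mice and mice with KΔ75, a loss-of-function mutation of DAP12. DAP12 is the adaptor through which receptors such as TREM2 signal in microglia. The series asks how the transcriptome differs between the genotypes. Each genotype had 4 samples, with 5975 to 7123 nuclei per WT sample and 7253 to 9505 per KΔ75 sample. The authors annotated 27669 excitatory neurons, 14073 inhibitory neurons, 10607 oligodendrocytes, 3258 astrocytes, 2249 microglia and 1688 nuclei of the class OPC. The total per sample ran from 93621219 to 121210544 UMIs in WT and from 74925912 to 102392910 in KΔ75. Tyrobp, the gene for DAP12, could not be looked up in any sample, because the count table has no gene names and the files do not pair its rows with genes, so the genotype labels rest on the authors alone. Smaller classes were VLMC (516 nuclei), Endo (324), ABC (267) and SMC (200).

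KΔ75 samples yielded more nuclei with fewer UMIs in each. A WT sample held 6623 ± 477 nuclei (mean ± SD, n = 4) and a KΔ75 sample 8590 ± 956. The median nucleus held 15717 ± 1231 UMIs in WT and 10163 ± 2276 in KΔ75, and 4533 ± 151 against 3573 ± 272 detected rows. Each of these 3 differences had p = 0.0286 in a two-sided exact permutation test, the smallest possible, and adjusted p = 0.0381. The mitochondrial share of UMIs was 0.0355% ± 0.0123 in WT and 0.0657% ± 0.0224 in KΔ75, which did not pass (exact permutation p = 0.0857). Lower depth was seen in every class. Excitatory neurons held a median of 21949 ± 2467 UMIs in WT and 13687 ± 3551 in KΔ75, oligodendrocytes 3351 ± 190 and 2238 ± 413, and microglia 3299 ± 265 and 2247 ± 364 (exact permutation, adjusted p = 0.0318 for each). The class ABC did not pass (p = 0.0571, exact permutation). All WT libraries and KΔ75 1 and 2 have names beginning with M_JE, and KΔ75 3 and 4 have names beginning with BCAE, so part of the contrast follows the library name. Among M_JE libraries, KΔ75 1 and 2 had medians of 13098 and 10743 UMIs and the lowest WT median was 14253. Those 6 libraries cannot give an exact permutation p below 0.0667. Without any 1 WT sample the adjusted p of the 3 measures rose to 0.0762, and over all alternatives it lay between 0.0286 and 0.0889 (exact permutation).

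**Figure D1:**
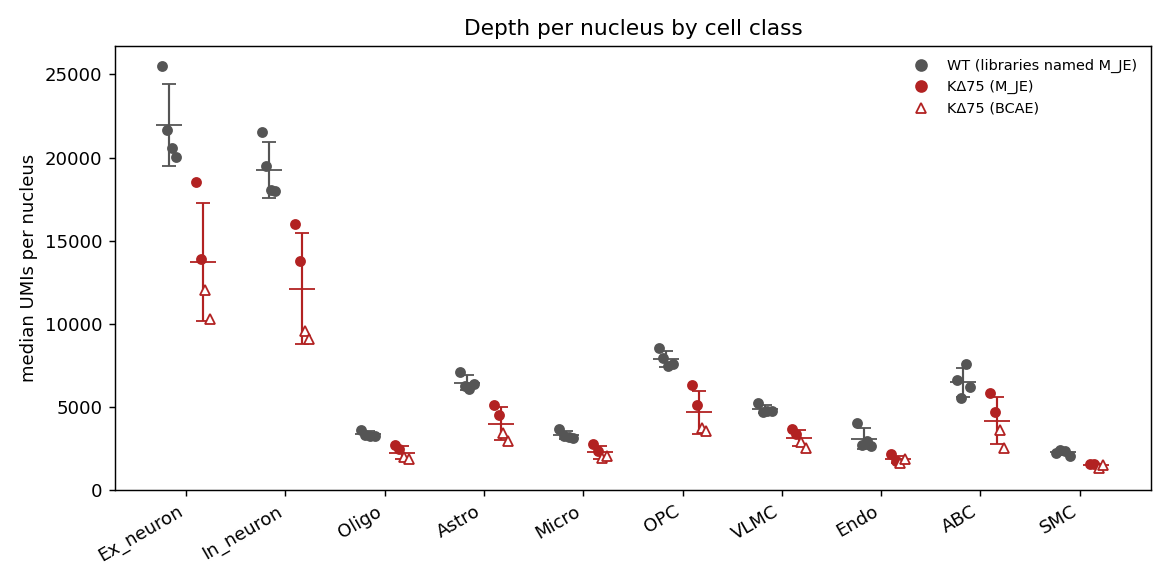
Median UMIs per nucleus (vertical axis) for each of the authors' cell classes, with a point per sample, bars for the mean and SD of 4 samples, and open triangles for KΔ75 libraries named BCAE. KΔ75 means lie below WT means in all 10 classes, for example 13687 against 21949 UMIs in excitatory neurons.

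No cell class passed the exact permutation test of its share of nuclei after adjustment. Excitatory neurons made up 43.0% ± 2.71 of nuclei in WT and 47.2% ± 2.28 in KΔ75 (n = 4 each, exact permutation p = 0.0857). Inhibitory neurons made up 23.2% ± 1.46 and 22.97% ± 0.699, and oligodendrocytes 19.3% ± 1.43 and 16.2% ± 2.07 (exact permutation p = 0.0857). Microglia, the class in which DAP12 acts, made up 3.95% ± 0.416 in WT and 3.53% ± 0.470 in KΔ75 (exact permutation p = 0.229). Astrocytes were at 5.14% ± 0.648 and 5.53% ± 0.126, and OPC at 2.77% ± 0.233 and 2.77% ± 0.196. The lowest p was that of VLMC nuclei, 1.07% ± 0.237 in WT and 0.683% ± 0.135 in KΔ75, lower in 4 of 4 KΔ75 samples than in any WT sample (exact permutation p = 0.0286, adjusted p = 0.171). Endo nuclei were at 0.665% ± 0.209 and 0.430% ± 0.0834 (exact permutation p = 0.0571, adjusted p = 0.171), SMC at 0.380% ± 0.0752 and 0.289% ± 0.0430, and ABC at 0.481% ± 0.169 and 0.414% ± 0.0702. A test of nuclei counts with edgeR's quasi-likelihood method called lower shares of VLMC (adjusted p = 0.0038), Endo (0.0196) and oligodendrocytes (0.0363). Within the KΔ75 group, oligodendrocytes averaged 17.7% in the M_JE and 14.7% in the BCAE libraries, VLMC 0.785% and 0.582%, and microglia 3.92% and 3.13%. Every nucleus in the table held at least 1001 UMIs, and the KΔ75 means of median depth were below the WT means in each class.

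**Figure D2:**
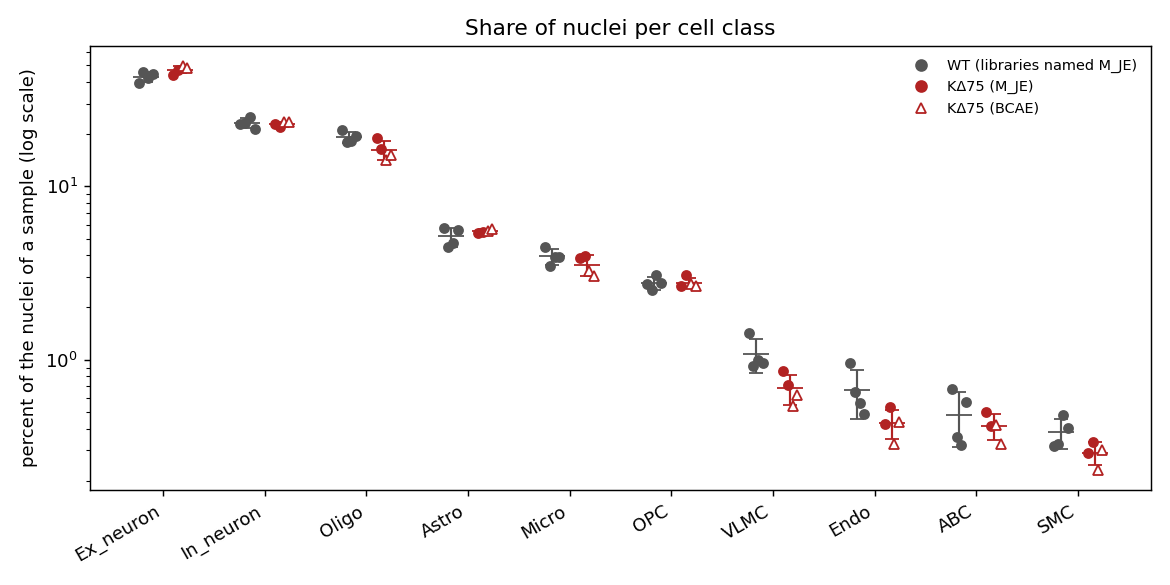
Percent of the nuclei of a sample in each of the authors' cell classes (vertical axis, log scale), with a point per sample and bars for the mean and SD of 4 samples per genotype. VLMC nuclei averaged 1.07% in WT and 0.683% in KΔ75, and open triangles are KΔ75 libraries named BCAE.

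Between 4 KΔ75 and 4 WT samples, 28 rows or fewer of the count table were called as changed in each cell class. This fit counts differences between the M_JE and BCAE libraries of KΔ75 as spread, so few calls do not mean that few rows differ. In microglia no row was higher and 8 were lower in KΔ75, of 9789 tested. In oligodendrocytes 14 were higher and 14 lower of 11990, in excitatory neurons 5 and 9 of 18555, in inhibitory neurons 2 and 6 of 16861, in OPC 4 and 7 of 10402, and in astrocytes 1 and 3 of 11446. VLMC had 0 higher and 2 lower, and SMC 3 higher and 1 lower. No row passed in Endo or ABC with edgeR, and DESeq2 called 0 and 4. An unadjusted edgeR p under 0.05 was seen in 264 of 3714 rows in Endo (7.11%) and 250 of 4172 in ABC (5.99%). Chance alone gives a fraction of about 0.05. The 79 calls covered 57 rows, of which 9 were called in 2 or more classes, all 9 in the same direction. Over all rows tested, called or not, the 4 KΔ75 values did not overlap the 4 WT values in 9.94% of rows in excitatory neurons, 8.03% in inhibitory neurons, 10.8% in oligodendrocytes and 6.36% in microglia, where chance gives 2.86%. In the other classes the share ran from 3.69% in ABC to 6.81% in astrocytes. Chance here assumes exchangeable samples, but the genotypes also differ in depth and library name. The excess is therefore not read as an effect of genotype.

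The 2 named rows that fell did so in neurons and in several glial classes. Row 19593 was called lower in 7 classes. In WT it was highest in microglia, at 84.8 ± 12.2 CPM (n = 4), and no UMI was counted in KΔ75 microglia against 334 in WT, which makes it at least 83.8-fold lower (edgeR adjusted p = 4.78e-05). It was also at 0 UMIs in KΔ75 astrocytes (at least 51.7-fold lower) and OPC (at least 38.3-fold lower). In excitatory neurons it went from 27.8 ± 2.81 CPM to 0.0795 ± 0.0555, or from 7718 UMIs to 20, a ratio of 338 with an exact Poisson interval of 219 to 553. Row 4892 was called lower in 6 classes. It stood at 280.1 ± 17.2 CPM in WT and 23.02 ± 5.21 in KΔ75 excitatory neurons (log2 fold change -3.67, SE 0.21, edgeR adjusted p = 1.31e-04). In OPC it stood at 129.2 ± 16.8 and 7.52 ± 3.93 CPM (log2 fold change -4.00, SE 0.26). In WT oligodendrocytes row 4892 stood at 3.78% ± 1.0996 of its level in excitatory neurons (n = 4), not above the 5.58% ± 0.559 at which neuron-enriched rows stood there, so its call in oligodendrocytes is not read as a fall in that class. Both kept their direction in each alternative tried. In oligodendrocytes, from 134 UMIs in WT and 4 in KΔ75, row 19593 missed the threshold without WT 1 (edgeR adjusted p = 0.0876), WT 2 (0.0765) or WT 3 (0.0805). In VLMC, from 82 UMIs and 1 (ratio 41.3, exact Poisson interval 7.20 to 1650), it did so without any 1 WT sample or without KΔ75 1 (edgeR adjusted p between 0.0637 and 0.0750).

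The 2 named rows that rose each passed the test in 1 class, one in OPC and the other in oligodendrocytes. Row 9540 rose in OPC from 65.9 ± 14.1 to 253.7 ± 49.7 CPM (log2 fold change 1.93, SE 0.17, edgeR adjusted p = 3.93e-05). Row 9540 was also higher in KΔ75, without passing, in the other 8 classes tested. Its log2 fold change was 1.65 in ABC (edgeR adjusted p = 0.053), 1.51 in microglia (0.184), 1.38 in VLMC (0.101), 1.18 in oligodendrocytes (0.0642) and 0.68 in excitatory neurons (0.0989). As a share of its WT level in excitatory neurons, row 9540 stood at 6.09% in oligodendrocytes, 6.58% in microglia and 50.8% in OPC. Neuron-enriched rows stood there at 5.58%, 11.9% and 8.64%. The higher values of row 9540 in oligodendrocytes and microglia are therefore not read as rises in those classes. Row 19023 rose in oligodendrocytes from 125.7 ± 7.35 to 254.2 ± 33.5 CPM (log2 fold change 0.97, SE 0.11, edgeR adjusted p = 0.0135). Row 19023 was far higher in excitatory neurons, at 2071 ± 105 CPM in WT and 2073 ± 131 in KΔ75, a difference within the spread between samples (edgeR adjusted p = 0.794). Its level in oligodendrocytes was 6.07% ± 0.283 of that in excitatory neurons in WT and 12.3% ± 1.99 in KΔ75 (n = 4), while neuron-enriched rows as a set stood there at 5.58% ± 0.559 and 8.81% ± 0.955. Row 19023 and the neuron-enriched rows thus both rose in these nuclei, the row by more than the set. Per oligodendrocyte nucleus row 19023 gave 0.453 UMIs in WT and 0.604 in KΔ75. How much of its rise follows that of the set was not tested. Without any 1 WT sample its adjusted p in oligodendrocytes lay between 0.0715 and 0.0876 (edgeR), and over all 19 alternatives between 1.27e-08 and 0.0876.

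**Figure D3:**
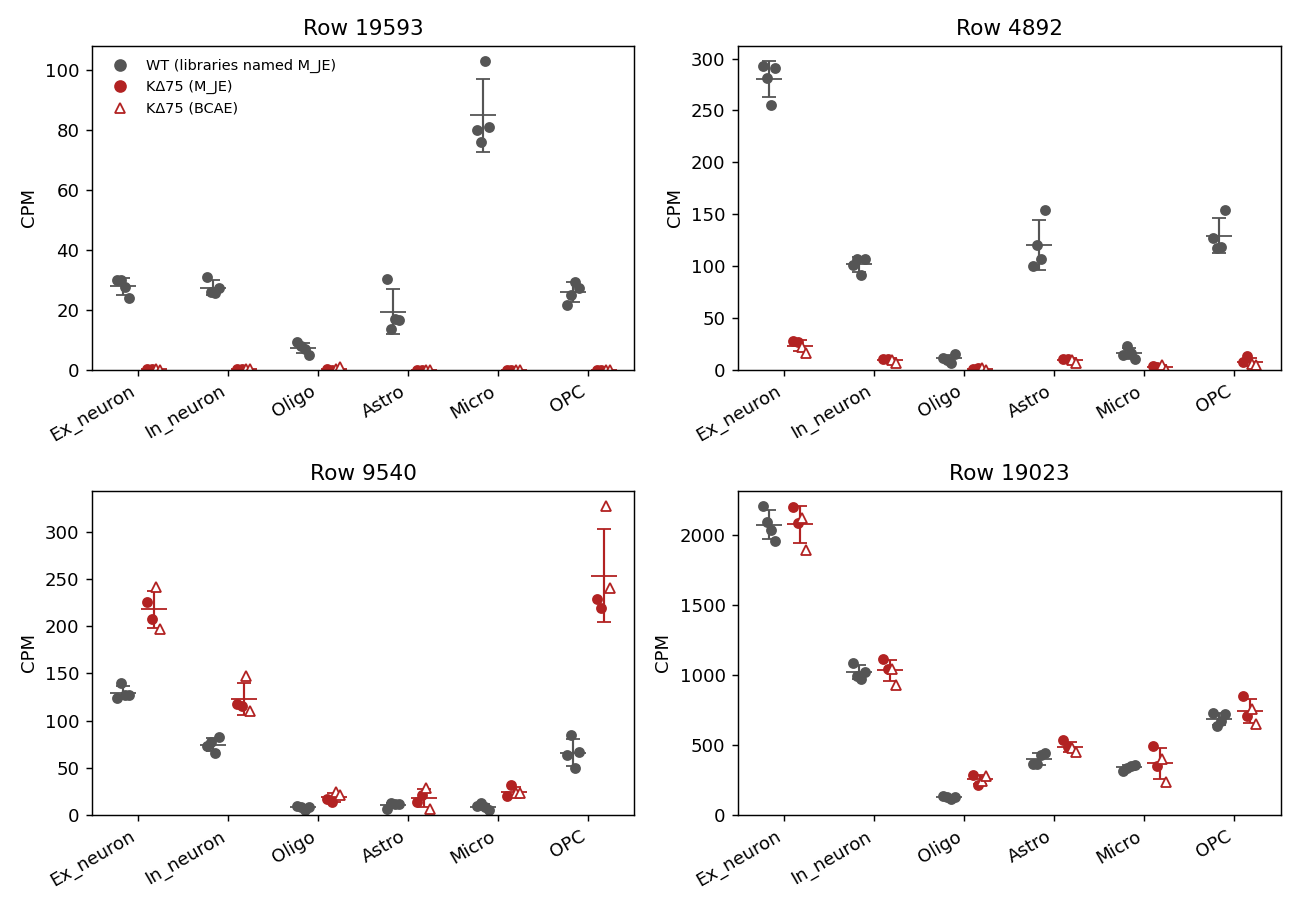
Level of the 4 named rows in CPM (vertical axes) in the 6 larger cell classes, with a point per sample and bars for the mean and SD of 4 samples per genotype. Row 19593 averaged 84.8 CPM in WT microglia and was at 0 in KΔ75 microglia, and row 9540 averaged 65.9 and 253.7 CPM in OPC.

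The number of changed rows depended on which libraries were compared. KΔ75 libraries named BCAE differed from KΔ75 libraries named M_JE, within 1 genotype, in 7806 rows in excitatory neurons, 3452 in oligodendrocytes, 2446 in OPC and 993 in microglia. Among the 6 M_JE libraries alone, KΔ75 1 and 2 differed from the 4 WT samples in 493 higher and 1735 lower rows in excitatory neurons, 342 and 927 in oligodendrocytes, and 58 and 250 in microglia. With the library name as a term in the fit of all 8 samples, these counts were 510 and 1872, 330 and 965, and 40 and 270. No WT library is named BCAE, so this fit takes the genotype difference from the 6 M_JE libraries and is no separate test. The main calls rest partly on the same libraries. The main calls were kept in the same direction with that term in 7 classes, for example 28 of 28 in oligodendrocytes and 8 of 8 in microglia, but only 1 of 4 was kept in SMC. The balance of higher and lower rows turned with the libraries. BCAE libraries of KΔ75 against WT gave 4155 higher and 3223 lower rows in excitatory neurons, 2403 and 1655 in oligodendrocytes, and 788 and 446 in microglia. DESeq2's Wald test on all 8 samples called 850 higher and 393 lower rows in excitatory neurons, 372 and 233 in oligodendrocytes, and 27 and 50 in microglia. Leaving out KΔ75 1 raised the edgeR count to 737 in excitatory neurons (616 higher and 121 lower) and 224 in oligodendrocytes (164 and 60), and leaving out WT 1 lowered them to 7 and 1.

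**Figure D4:**
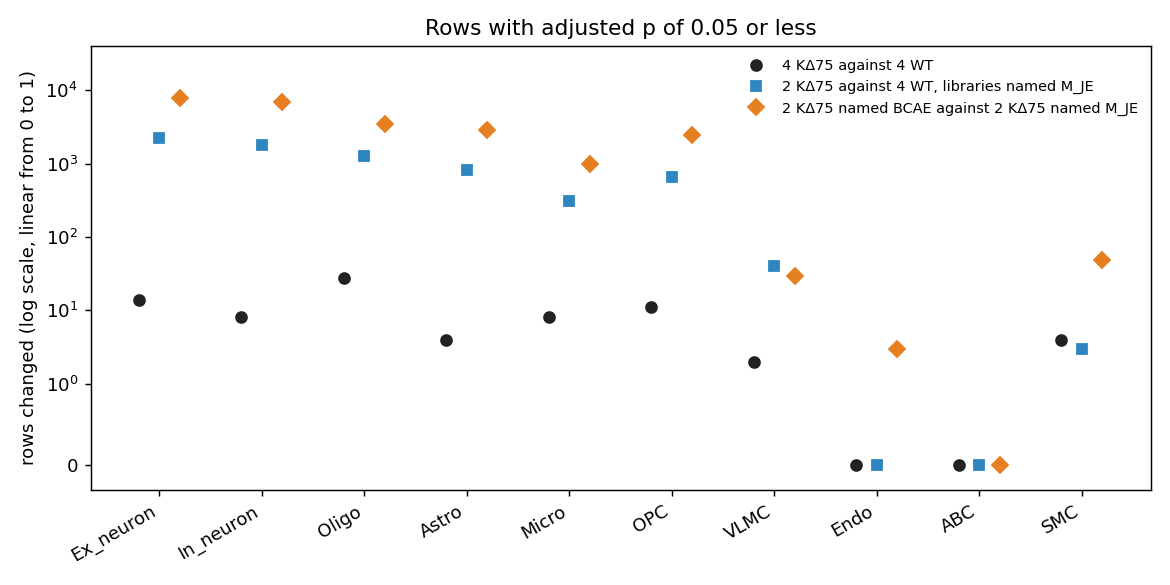
Number of rows with an adjusted p of 0.05 or less (vertical axis, log scale above 1) in each cell class for the comparison of all 8 samples, for the M_JE libraries alone, and for the BCAE against the M_JE libraries of KΔ75. In excitatory neurons these numbers were 14, 2228 and 7806.

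Neuron-enriched rows were higher in KΔ75 glial nuclei relative to all UMIs, but not in UMIs per nucleus. In oligodendrocytes 165 of the 167 tested rows of this set were higher, with a median log2 fold change of 0.71 (camera adjusted p = 5.84e-36, and adjusted p = 0.0303 with an estimated correlation). Only 1 of them passed over all rows, and 99 rose and 1 fell when adjusted over the list alone. The set was also called in astrocytes (median 0.55, camera adjusted p = 9.78e-23), OPC (0.26, 1.60e-08) and microglia (0.21, 0.00411). With an estimated correlation the adjusted p was 0.17 in astrocytes, 0.341 in OPC and 0.525 in microglia, so of these 4 classes only the call in oligodendrocytes held. Outside the glia the set was also called higher in SMC, where 11 of 12 tested rows were higher (median 0.89, camera adjusted p = 1.05e-06, and adjusted p = 0.0312 with an estimated correlation), and lower in Endo, where 26 of 83 were higher (median -0.20, camera adjusted p = 0.0491, and adjusted p = 0.850 with an estimated correlation). Sets of some other classes were also called higher in oligodendrocytes. Rows enriched in SMC had a median of 0.50 there (20 of 25 higher, camera adjusted p = 0.00058, and adjusted p = 0.0303 with an estimated correlation), and rows enriched in astrocytes a median of 0.28 (57 of 74 higher, camera adjusted p = 0.00445, and adjusted p = 0.151 with an estimated correlation). The astrocyte rows took 0.197% to 0.214% of the UMIs of oligodendrocytes in WT samples and 0.209% and 0.217% in KΔ75 1 and 2, against 0.302% and 0.307% in KΔ75 3 and 4, so only the BCAE libraries stood apart. Neuron-enriched rows were higher in oligodendrocytes both among M_JE libraries (median 0.66) and for BCAE libraries against WT (0.73). The set took 0.490% ± 0.0524 of the UMIs of WT and 0.758% ± 0.0703 of those of KΔ75 oligodendrocytes (n = 4, exact permutation p = 0.0286, adjusted p = 0.0571). Per nucleus it gave 17.6 ± 2.56 UMIs in WT and 18.1 ± 4.15 in KΔ75, while all rows together gave 3576 and 2379. In the other glial classes the set gave fewer UMIs per nucleus in KΔ75. It stood at 0.823 times WT in astrocytes, 0.701 in microglia and 0.674 in OPC, none past the threshold (exact permutation, adjusted p of 0.171 or more). Suspected doublets made up 4.23% to 9.41% of nuclei in WT and 0.941% to 3.60% in KΔ75 samples. Both marks rest on UMI counts without regard to genotype, so they can take out more of the deeper WT nuclei. Without suspected doublets the share of the set was higher in KΔ75 in all 4 glial classes, for example 0.433% ± 0.0470 in WT and 0.690% ± 0.0852 in KΔ75 microglia (n = 4, exact permutation, adjusted p = 0.0286). In microglia the difference passed only after this unequal removal. With all nuclei the share there was 1.05% ± 0.0834 in WT and 1.099% ± 0.127 in KΔ75 (exact permutation p = 0.514).

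**Figure D5:**
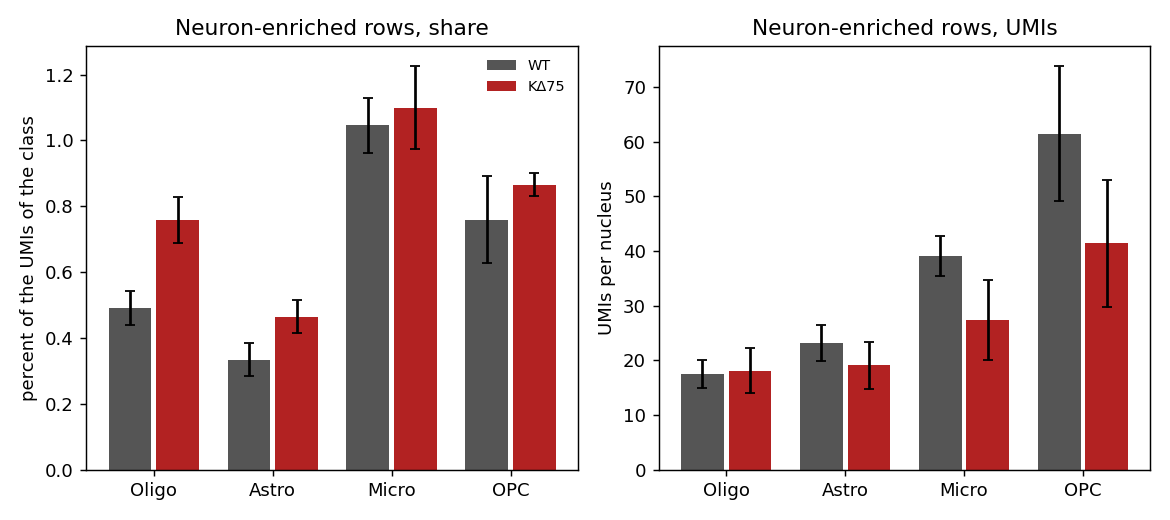
Share of UMIs (left, percent) and UMIs per nucleus (right) from 220 neuron-enriched rows in 4 glial classes, as means with SD over 4 samples per genotype. In oligodendrocytes the share was 0.490% in WT and 0.758% in KΔ75, and the UMIs per nucleus were 17.6 and 18.1.

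Rows enriched in a glial class itself moved apart between the KΔ75 libraries, with medians near 0 over all 8 samples except in oligodendrocytes. In microglia 218 of 515 rows were higher in KΔ75 (median log2 fold change -0.055, camera adjusted p = 0.0685). Astrocyte rows (median -0.00029, camera adjusted p = 0.562) and OPC rows (-0.030, 0.320) were not called. Oligodendrocyte rows were called lower in oligodendrocytes (median -0.12, camera adjusted p = 0.000355), with adjusted p = 0.481 with an estimated correlation. Among the M_JE libraries alone the medians turned positive, at 0.13 in microglia, 0.15 in astrocytes, 0.12 in OPC and 0.048 in oligodendrocytes, and the sets of microglia and astrocytes were then called higher. For the BCAE libraries of KΔ75 against WT all 4 sets were called lower, with medians of -0.28 in microglia, -0.25 in astrocytes, -0.29 in OPC and -0.36 in oligodendrocytes. Oligodendrocyte rows took 13.4% to 14.2% of the UMIs of oligodendrocytes in WT samples, 13.8% and 14.8% in KΔ75 1 and 2, and 11.3% and 10.7% in KΔ75 3 and 4. Rows enriched in excitatory neurons (median -0.031) and inhibitory neurons (-0.022) were not called in their own class (camera adjusted p = 0.272 and 0.0889).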

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

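The tests of free RNA, of the order of rows and of differences between classes were chosen only after the result was seen, and the test of depth was planned before its result was seen.

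In 3 of the 58 groups of 4 samples that were looked at, 1 sample lay far from the other 3, where chance gives about 1 in 20 groups. KΔ75 2 had 3.07% OPC nuclei where the other KΔ75 samples had 2.66% to 2.71%. WT 1 had 1.43% VLMC nuclei where the other WT samples had 0.921% to 0.997%. Row 19593 stood at 2.45 CPM in VLMC of KΔ75 1, from 1 UMI, and at 0 in the other KΔ75 samples.

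The log2 fold changes of both risen rows were compared between cell classes. Each row had been chosen for its smallest p in 1 class of the same samples, so these exact permutation tests favour that class and do not show that a rise belongs to it. The value of row 9540 in OPC exceeded that in excitatory neurons by 1.196, in inhibitory neurons by 1.23, in oligodendrocytes by 0.72 and in astrocytes by 1.35 (adjusted p = 0.04 each, exact permutation). It did not differ past the threshold from microglia (0.43, exact permutation p = 0.257), VLMC (0.59, p = 0.143) or ABC (0.32, p = 0.457). The value of row 19023 in oligodendrocytes exceeded that in excitatory neurons by 1.01, in inhibitory neurons by 0.99, in astrocytes by 0.71, in microglia by 0.94, in OPC by 0.90 and in VLMC by 1.13 (adjusted p = 0.04 each, exact permutation), but not past the threshold that in ABC (0.61, p = 0.286). Neuron-enriched rows rose as a set in oligodendrocytes too, by a median of 0.71.

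For the fall of rows 19593 and 4892 in excitatory neurons, a difference in summed depth is argued against. After thinning to the shallowest sample row 19593 was still called there, with a log2 fold change of -8.34. Row 4892 kept its call there in all 20 alternatives, thinning among them, with log2 fold changes from -4.04 to -3.37. Thinning of sums could not test the lower depth per nucleus. Free RNA from neurons was tested in WT glia by the level of a row as a share of that in excitatory neurons, divided by the same share of the neuron-enriched rows. It is argued against for row 19593 in oligodendrocytes (4.59), astrocytes (18.8), microglia (26.1) and OPC (11.2) and for row 4892 in astrocytes (11.6) and OPC (5.46), but stays open for row 4892 in oligodendrocytes (0.67), where the call may only follow the fall in neurons. A linked stretch of the genome or a strain variant also stays open. The 57 called rows held 26 pairs within 50 rows of each other in the table, against a mean of 6.36 in 10000 random draws. The permutation p was 1e-04, the smallest these draws can give. This is 4.09 times the mean, against 1.08 times for 384 rows of another split of the samples. Rows 19593 and 9540 each had other called rows within 50 rows. Row 4892 had none, so the order of rows does not bear on its fall. The files do not say that the table follows the genome.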

How the results depend on the processing

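The alternatives by library name, surrogate variables, suspected doublets, agreement of both clusterings and sets of rows were chosen after seeing the data, and the others were planned. Not run were the sex covariate, doublets and classes named by marker genes, and gene lists with Tyrobp, since the rows carry no gene names. The number of changed rows was the result that moved most. Of 210 alternative counts, 77 stayed within 1.5 times the reported count. With 2 surrogate variables as terms there were 2423 in excitatory neurons, 1060 in inhibitory neurons, 834 in oligodendrocytes, 392 in astrocytes, 53 in microglia, 309 in OPC, 1 in VLMC, 3 in ABC and 0 in SMC. DESeq2's Wald test gave 1243 in excitatory neurons, 670 in inhibitory neurons, 605 in oligodendrocytes, 112 in astrocytes, 77 in microglia, 64 in OPC, 11 in VLMC, 4 in ABC and 1 in SMC. With the library name as a term there were 2382 in excitatory neurons, 2081 in inhibitory neurons, 1295 in oligodendrocytes, 809 in astrocytes, 310 in microglia, 670 in OPC, 33 in VLMC and 2 in SMC. Among M_JE libraries alone there were 2228 in excitatory neurons, 1808 in inhibitory neurons, 1269 in oligodendrocytes, 808 in astrocytes, 308 in microglia, 657 in OPC and 40 in VLMC. For the BCAE libraries of KΔ75 against WT there were 7378 in excitatory neurons, 6190 in inhibitory neurons, 4058 in oligodendrocytes, 2064 in astrocytes, 1234 in microglia, 1924 in OPC, 37 in VLMC, 13 in Endo, 8 in ABC and 80 in SMC. Without a filter on low counts there were 184 in oligodendrocytes, 72 in astrocytes, 94 in microglia, 331 in OPC, 49 in VLMC, 51 in Endo, 43 in ABC and 20 in SMC. With counts thinned to the shallowest sample there were 4 in microglia, 1 in VLMC and 2 in SMC. Without suspected doublets there were 40 in microglia, 19 in OPC, 1 in Endo, 2 in ABC and 0 in SMC. On nuclei where both clusterings gave 1 class there were 5 in microglia. On rows at 0.1 or more of their highest class there were 5 in inhibitory neurons, 9 in oligodendrocytes, 1 in ABC and 0 in SMC. With 1 adjustment over all classes there were 13 in oligodendrocytes, 5 in microglia, 6 in OPC, 1 in ABC and 1 in SMC. With DESeq2's size factors in edgeR there was 1 in ABC. With 1 sample left out, counts ranged from 7 to 737 in excitatory neurons, 3 to 115 in inhibitory neurons, 1 to 224 in oligodendrocytes, 2 to 6 in astrocytes, 1 to 18 in microglia, 4 to 75 in OPC, 1 to 5 in VLMC, 0 to 2 in Endo and 0 to 18 in SMC. Without WT 1 it was 7 in excitatory neurons, 3 in inhibitory neurons, 1 in oligodendrocytes, 2 in astrocytes, 1 in microglia, 4 in OPC, 1 in VLMC and 0 in SMC. Without WT 2 it was 8 in excitatory neurons, 3 in inhibitory neurons, 1 in oligodendrocytes, 2 in astrocytes, 3 in microglia, 4 in OPC, 1 in VLMC and 0 in SMC. Without WT 3 it was 7 in excitatory neurons, 5 in inhibitory neurons, 1 in oligodendrocytes, 2 in astrocytes, 4 in OPC, 1 in VLMC, 2 in Endo and 0 in SMC. Without WT 4 it was 8 in excitatory neurons, 3 in inhibitory neurons, 2 in oligodendrocytes, 2 in astrocytes, 4 in microglia, 4 in OPC, 1 in VLMC and 2 in SMC. Without KΔ75 1 it was 737 in excitatory neurons, 115 in inhibitory neurons, 224 in oligodendrocytes, 7 in OPC, 1 in VLMC and 10 in SMC. Without KΔ75 2 it was 3 in inhibitory neurons, 188 in oligodendrocytes, 18 in microglia, 75 in OPC and 18 in SMC. Without KΔ75 3 it was 8 in excitatory neurons, 4 in inhibitory neurons, 9 in oligodendrocytes, 2 in astrocytes, 5 in VLMC and 8 in SMC. Without KΔ75 4 it was 9 in excitatory neurons, 4 in inhibitory neurons, 65 in oligodendrocytes, 26 in OPC, 5 in VLMC and 1 in SMC. No row changed in Endo or ABC in most of these settings. Fewer samples, more rows tested or an added term set these fits apart. The spread between samples that edgeR fitted, as a coefficient of variation, fell when the library name was a term. It was 0.252 without and 0.138 with that term in excitatory neurons, 0.226 and 0.131 in oligodendrocytes, and 0.218 and 0.156 in microglia. The main fit thus counts the difference between library names within KΔ75 as spread. How far this sets the counts was not tested.

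For shares of nuclei, 120 of 130 alternative values kept their direction and stayed short of the threshold. The edgeR test of nuclei counts called oligodendrocytes (log2 fold change -0.26), VLMC (-0.67) and Endo (-0.64). Among non-neuronal nuclei microglia turned higher by 0.111 percentage points, and without suspected doublets OPC turned lower (-0.0674). With 1 sample left out the difference ranged from -0.831 to 0.35 points in inhibitory neurons and from -0.0889 to 0.111 in OPC. For yield, differences kept their direction. With 1 sample left out they ranged from 1662 to 2412 nuclei, -6532 to -4816 median UMIs, -1090 to -886 detected rows and 0.0212 to 0.0393 percentage points of mitochondrial UMIs, which passed without KΔ75 1. Among M_JE libraries they were 1342 nuclei, -3796 UMIs and -778 rows, short of the threshold because 6 libraries allow no smaller p than 0.0667.

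Neuron-enriched rows kept their direction in all 76 alternative values and their call in 66. With an estimated correlation the adjusted p was 0.17 in astrocytes, 0.525 in microglia and 0.341 in OPC, and with fry 0.0708, 0.345 and 0.188. In microglia the call was also lost for BCAE libraries (median 0.29) and where both clusterings gave 1 class (0.026), and ranged from 0.169 to 0.297 with 1 sample left out (lost without KΔ75 1 or 3). Medians of rows enriched in the class itself were, with the library name as a term, 0.056 in oligodendrocytes, 0.16 in astrocytes, 0.13 in microglia and 0.12 in OPC. Among M_JE libraries they were 0.048 in oligodendrocytes, 0.15 in astrocytes, 0.13 in microglia and 0.12 in OPC. For BCAE libraries they were -0.25 in astrocytes, -0.28 in microglia and -0.29 in OPC. Without a filter they were -0.032 in astrocytes, -0.087 in microglia and -0.076 in OPC. Without suspected doublets they were -0.12 in microglia. In oligodendrocytes the adjusted p was 0.481 with an estimated correlation and 0.293 with fry. With 1 sample left out these medians ranged from -0.188 to -0.05 in oligodendrocytes, -0.105 to 0.0608 in astrocytes, -0.166 to 0.0083 in microglia and -0.116 to 0.0386 in OPC. The cause was not tested.

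No clear pairing of the samples by replicate number was seen. The check cannot exclude a pairing, since KΔ75 samples also differed by library name. Of 24 same-number pairs over 6 classes, 6 correlated above 0.1 (range -0.259 to 0.182), and 7 of 24 WT samples correlated best with their own number. With the replicate block there were 3 in excitatory neurons, 3 in inhibitory neurons, 0 in oligodendrocytes, 1 in astrocytes, 4 in OPC, 1 in VLMC, 9 in ABC and 13 in SMC. With the block, rows enriched in microglia were called lower in microglia (median -0.088), and an exact sign-flip test of shares cannot go below p = 0.125.

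The 4 named rows kept their direction in all 296 alternative values and their call in 273. In oligodendrocytes calls were lost without WT 1, 2 or 3 for rows 19593, 4892 and 19023, without WT 4 for rows 4892 and 19023, and without KΔ75 3 for row 4892. In VLMC the call of row 19593 was lost without any 1 WT sample, without KΔ75 1 and with 2 surrogate variables. With the replicate block the calls in oligodendrocytes and those of row 19593 in VLMC and astrocytes were lost. Thinning to the shallowest sample left the counts of 13 in excitatory neurons, 8 in inhibitory neurons, 30 in oligodendrocytes and 11 in OPC near those at full depth. The difference in summed depth between samples thus did not set the counts in these 4 classes. In microglia the count fell from 8 to 4, in astrocytes from 4 to 3, in VLMC from 2 to 1 and in SMC from 4 to 2. On simulated data at the real depth and spread, 1.5-fold changes were recovered in 4.48% of cases in microglia.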

Other observations

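The tests of structure within a genotype, of genotype, of doublets, of depth in glia and of the splits by number of rows were chosen only after the result was seen. The tests of thinning among M_JE libraries, of correlated rises and of the splits by the median of neuron-enriched rows were written before their results were seen.

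Within the neurons, 27 clusters of the authors were compared as shares of their class, and none passed adjustment (lowest adjusted p = 0.193, exact permutation). Cluster 12 held 5.22% ± 0.933 of excitatory neurons in WT and 8.22% ± 0.770 in KΔ75, higher in 4 of 4 samples (n = 4, exact permutation p = 0.0286). Cluster 21 held 6.15% ± 1.06 and 7.69% ± 0.354 of inhibitory neurons (n = 4, exact permutation p = 0.0286). Clusters 2 and 20 of the excitatory neurons were lower, at 13.6% ± 0.393 and 12.6% ± 0.425, and 4.75% ± 0.558 and 3.91% ± 0.265 (n = 4, exact permutation p = 0.0286 each).

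Of the 13 mitochondrial rows, 12 had higher means over all nuclei in KΔ75, by 1.44 to 3.36 times. The other stood at 3.91 ± 1.61 CPM in WT and 0.496 ± 0.133 in KΔ75 (n = 4), and its highest KΔ75 value, 0.627, lay below the lowest WT value, 2.12. Rows expressed within 4-fold in all classes were lower as a set in KΔ75 excitatory neurons (median log2 fold change -0.090, camera adjusted p = 7.06e-08, and adjusted p = 0.00148 with an estimated correlation) and inhibitory neurons (median -0.078, camera adjusted p = 3.28e-06, and adjusted p = 1e-04 with an estimated correlation). In oligodendrocytes their median was -0.064 (camera adjusted p = 3.12e-05, and adjusted p = 0.00794 with an estimated correlation), and they were not called in astrocytes, microglia or OPC. As a set, mitochondrial rows were called higher in excitatory neurons (median 0.92), inhibitory neurons (1.04) and OPC (0.59) and lower in astrocytes (-0.44), but with an estimated correlation the adjusted p was 0.411, 0.161, 0.341 and 0.291. They were also called with the preset alone in Endo (median -0.33), ABC (0.25) and SMC (0.70). Rows enriched in inhibitory neurons were called higher in excitatory neurons (median 0.26, camera adjusted p = 0.00491, and adjusted p = 0.0343 with an estimated correlation). Rows enriched in VLMC, 5 of them tested, were called lower in ABC (median -1.31, camera adjusted p = 2.11e-08, and adjusted p = 0.0133 with an estimated correlation). In the smaller classes, rows enriched in the class itself were called lower in ABC (median -0.064, camera adjusted p = 0.0275, and adjusted p = 0.787 with an estimated correlation) and not called in VLMC, Endo or SMC.

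Many rows were lower in KΔ75 1 and 2 than in WT among libraries named M_JE. A difference in summed depth is argued against, since 2198 rows were still called in excitatory neurons after thinning these libraries, against 2228 before. The sums of KΔ75 1 and 2 there, 65091685 and 65981167 UMIs, already lay within the WT range of 59819501 to 74935553. Thinning of sums could not test the lower depth per nucleus, which stays open. Structure among samples of 1 genotype stays open. WT 1 and 3 differed from WT 2 and 4 in 323 rows in excitatory neurons, and the other 2 WT splits called 0. Comparisons of KΔ75 1 and 2 with 2 WT samples called more, from 877 to 1981 rows, the most against WT 1 and 3. Genotype cannot be told apart from the library name in KΔ75 3 and 4. In excitatory neurons, rows called in KΔ75 1 and 2 against 2 WT samples had the same sign in KΔ75 3 and 4 against the other WT samples in 48.3% of cases (SD 7.47 over 6 choices of WT samples, 50.9% by chance). The bound of 55%, set after the values were seen, lies within that spread. By choice of WT samples for KΔ75 1 and 2, the share ran from 36.2% (WT 1 and 3) to 56.9% (WT 2 and 4). The share was 46.0% in inhibitory neurons (50.8% by chance), 50.4% in OPC (50.4%), 53.9% in astrocytes (50.02%), 58.5% in microglia (51.0%) and 60.8% in oligodendrocytes (49.6%), with SDs of 7.16 to 9.19.

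The rise of neuron-enriched rows in glia was weighed against doublets, free RNA and depth. Doublets stay open, although the median log2 fold change in oligodendrocytes was 0.69 without suspected doublets and 0.71 with them. Neuronal rows did not mark a doublet, so oligodendrocytes joined with neurons were mostly left out only through the top 2% of UMIs. Free RNA and lower depth stay open and may act together. Across the 220 rows, which are not independent replicates, the rise in CPM in oligodendrocytes correlated with that in astrocytes at a Spearman rho of 0.852. Rows at a higher level rise by more CPM under any proportional change, so this correlation does not single out free RNA. The set gave 1.03 times as many UMIs per oligodendrocyte nucleus in KΔ75 as in WT while all other UMIs were fewer. With all nuclei that ratio was 0.823 in astrocytes, 0.701 in microglia and 0.674 in OPC. Without suspected doublets it was 0.964 in astrocytes, 1.099 in microglia and 0.817 in OPC. No effect of genotype on the glia was tested apart from depth.

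Other splits of the 8 samples into 4 and 4, 35 in all with the real one, bear on the counts of changed rows. In 6 classes 2 splits, counting the real one, called at least the real number of rows, so chance was not excluded. The real and the highest other counts were 14 and 384 in excitatory neurons, 8 and 449 in inhibitory neurons, 28 and 187 in oligodendrocytes, 4 and 168 in astrocytes, 8 and 51 in microglia, and 11 and 175 in OPC. The highest other split in these classes sets WT 1, WT 3, KΔ75 3 and KΔ75 4 against the rest, and with several times the real count it points to a structure of the samples. It keeps both BCAE libraries together. In VLMC 2 splits, counting the real one, reached the real count of 2 (highest other 2). In Endo and ABC all 35 splits reached the real count of 0, with highest other counts of 2 and 50. In SMC 1 split, the real one, reached 4 rows, against a highest other count of 3. This is the smallest number of splits possible, in 1 of 10 classes, and no row passed there with edgeR without WT 1, 2 or 3, so chance is left open. Of the rows that the other split called, oligodendrocytes shared 156 with excitatory neurons, where 5.08 would be shared if the lists were independent.

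For the median of neuron-enriched rows, the real split of 35 was the highest in oligodendrocytes (1 split, 0.71 against a highest other of 0.49) and in astrocytes (1 split, 0.55 against 0.50). A single split of 35 is the smallest result possible and 4 classes were tested. With all nuclei the exact permutation test of the share of the set gave adjusted p = 0.0571 in both. Without suspected doublets, marked after seeing the data, that test gave adjusted p = 0.0286 in both, the smallest possible. Chance is therefore left open in both. Counting the real split, 4 splits reached the real median of 0.21 in microglia (highest other 0.28) and 3 reached 0.26 in OPC (highest other 0.30), so chance was not excluded.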
